A study of Rattus norvegicus with 46 samples.

How the data were processed

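Gene counts of 46 bulk RNA libraries were taken as deposited, 23 from liver and 23 from quadriceps muscle of rats given vehicle, food restriction to a matched weight, or CagriSema. The values are whole-number counts per gene, not normalized, in 1 table of the whole series with 32552 genes under Ensembl identifiers and symbols. Per the labels' protocols, RNA was extracted with an RNeasy Minikit and libraries were made with a Twist UMI system, in which molecular identifiers mark single RNA molecules. Per the submitters' processing notes, fastp 0.23.1 and STAR 2.5.2b were used. The genome build, the annotation, the program that counted reads and whether molecular identifiers were used in counting are not given in the sources used here. Columns were matched to libraries by their titles, and 1 count column that matched no library was not used. Genes keep the identifiers and symbols of the table, which stand behind every value here, and no coordinates were used.

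Totals per library were 9888858 to 16525274 counts. A count of 0 in 1 library allows up to 0.188 to 0.303 CPM in liver and 0.182 to 0.262 CPM in quadriceps, taking 3 counts as the floor. No pair of libraries was near-identical: over 253 pairs per tissue, the lowest chi-square per degree of freedom between the counts of a pair was 16.8 in liver and 6.97 in quadriceps. Groups were taken from the treatment labels, and no batch is named there.

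Tests were run in R 4.3.3. Within a tissue, edgeR 4.0.16 fitted a negative binomial model with quasi-likelihood F tests and robust estimation to the 3 groups, which share 1 estimate of the spread. Genes were kept with filterByExpr, libraries were scaled with TMM, and p-values were adjusted by Benjamini-Hochberg over the genes tested, 12702 in liver and 12471 in quadriceps, with a threshold of 0.05. Each adjusted p of a single gene in the text is from this test unless another tool is named. Standard errors of log2 fold changes were computed from the same fits. CPM values use TMM-scaled library sizes and are given as mean ± SD of a group. Whether a change differed between liver and quadriceps was tested as an interaction over all 46 libraries and 14110 genes in the same way.

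Gene lists of pathways and cell types were fixed before the data were examined, 32 for liver and 30 for quadriceps. Those with at least 5 tested genes, 27 and 28, were tested with camera in limma 3.58.1 on voom log2 CPM values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a tissue. The same lists were tested with camera and an estimated correlation and with fry. For 25 list genes no row was matched, and they were not analysed here. For 8 list genes an older symbol was matched through a table of rat gene names. Counts of changed list members are given over all genes tested and adjusted over the list alone.

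Genes were named by a rule set before the data were examined. It took, in each comparison, the 3 largest increases and the 3 largest decreases among genes past the threshold with a mean of at least 1 CPM and a proper symbol. It added up to 2 members with the lowest p, among those past the threshold, of each core list of the tissue. It also took Glp1r, Calcr, Ramp1, Ramp2 and Ramp3 in both tissues, Fgf21, Cyp7a1, Igf1 and Scd in liver, and Ucp1, Ucp2, Ucp3 and Sln in quadriceps, whether or not they changed. For the interaction it took up to 4 genes per comparison with the lowest p. Of the genes so taken, 1 is not reported here. Other names were chosen after the values were seen and are said to be so.

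Fold changes against vehicle were compared between CagriSema and weight matching by Pearson correlation and covariance across genes. Because both share the vehicle libraries, 20 simulations and 35 splits of the vehicle libraries, with 1 part for each comparison, were run beside them. In each simulation the counts of all 3 groups, vehicle included, were drawn with no difference between groups. Simulated genes were independent and no library was set apart, so agreement through an outlying vehicle library is not in the simulated values. For genes called with weight matching, the agreement was computed again in 20 such simulations and 35 such splits, a choice made after the data were seen. There, the full quasi-likelihood fit was repeated and as many genes as had been called were taken by the lowest p. The whole procedure was tested on simulated counts with 200 changed genes per comparison. At a log2 change of 1, the test recovered 74.2% of changed genes for CagriSema against vehicle, 81.8% for weight matching against vehicle and 78.8% for CagriSema against weight matching in liver, and 77.3%, 90.9% and 84.8% in quadriceps. At a log2 change of 0.5 it recovered 35.3%, 55.9% and 36.8% in liver and 55.9%, 54.4% and 61.8% in quadriceps. The share of false calls was 3.55%, 5.52% and 5.30% in liver and 3.18%, 2.42% and 5.92% in quadriceps. The simulated genes were independent, had 1 spread over all 3 groups and held no library set apart. These shares therefore hold for such data only, and do not measure false calls in the deposited counts.

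Alternatives set before the data were examined were the DESeq2 1.42.0 Wald test, RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 7 libraries, non-robust estimation, limma voom with library quality weights, fits of the 2 groups compared alone, leaving out each library in turn, and the library number as a block across tissues. Added after the data were seen were fits without liver vehicle libraries 4 and 6, without quadriceps vehicle libraries 2 and 5, and with a slow-fibre score as a covariate in quadriceps. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.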

Results

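Livers and quadriceps muscles of DIO (diet-induced obese) rats were profiled by bulk RNA sequencing in 3 groups. CagriSema combines cagrilintide, a long-acting analog of the hormone amylin, with semaglutide, an agonist of the GLP-1 receptor. The weight-matched group had its food restricted to a matched body weight, and the vehicle group was the control. The design text gives 20 days of treatment for the liver and was not taken to hold for muscle. Liver counts covered 8 vehicle, 8 weight-matched and 7 CagriSema libraries, and quadriceps counts covered 7, 8 and 8. Library totals ran from 9888858 to 15948219 counts in liver and from 11462369 to 16525274 counts in quadriceps. The labels do not say that each library came from a separate rat, so the p-values measure the spread between these libraries.

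Some vehicle libraries stood apart from the rest of their group. In liver, vehicle library 4 lay at 134 on the first principal component, which held 35.9% of the variance. Genes of ribosomal proteins took 1.84% of its counts, against 0.649% to 0.940% in the other 22 liver libraries. Vehicle library 6 lay at 39.1 on the same component, and mitochondrially encoded genes took 9.29% of its counts against 4.09% to 5.81% elsewhere in liver. In quadriceps, vehicle library 8 had the most extreme place on the first component, at 39.4. Mitochondrially encoded genes took 22.8% of its counts, the highest share in that tissue. Vehicle libraries 2 and 5 lay at 43.8 and 40.5 on the second component, which held 16.8% of the variance. The counts of all genes changed against vehicle are therefore also given without liver libraries 4 and 6 and without quadriceps libraries 2 and 5. This choice was made after the data were seen. Those fits kept quadriceps vehicle library 8. With it alone left out, 191 genes passed for weight matching against vehicle and 7 for CagriSema against vehicle.

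**Figure D1:**
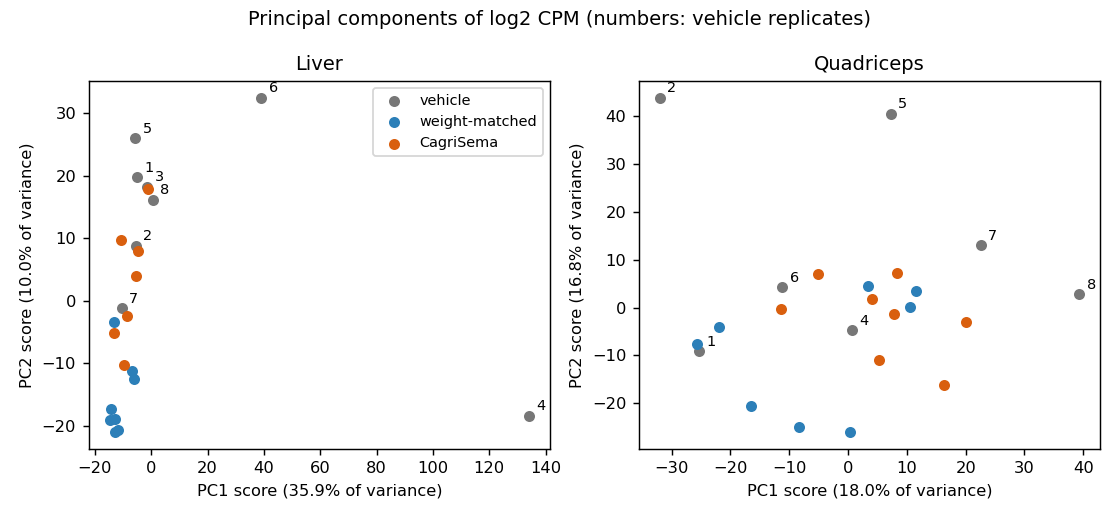
First and second principal components of log2 CPM in liver and in quadriceps, 1 point per library, coloured by group. Liver vehicle library 4 lies at 134 on the first axis and vehicle library 6 at 39.1.

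In the liver, the comparison of weight-matched with vehicle rats asked what food restriction alone did. Of the 19 tested genes of the lipogenesis list, 11 fell, none rose and 8 did not pass the test. Scd (ENSRNOG00000013552), which encodes the desaturase that makes monounsaturated fatty acids, fell from 2517 ± 2001 CPM (SD, n = 8) to 266 ± 150 CPM (n = 8). Pnpla3 (ENSRNOG00000022268), a lipid-droplet gene switched on by feeding, fell from 317 ± 489 to 4.47 ± 3.31 CPM. Of 28 genes of amino acid breakdown 9 fell, 1 rose and 18 did not pass. Oat (ENSRNOG00000016807), the ornithine aminotransferase gene, fell from 330 ± 113 to 109 ± 22.4 CPM.

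Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 892 of 12702 genes, 316 higher and 576 lower in weight-matched rats, and 207 of them by more than 2-fold. Scd changed by -3.24 ± 0.56 (log2 fold change ± SE, adjusted p = 0.00142), Pnpla3 by -6.15 ± 1.07 (adjusted p = 0.00144) and Oat by -1.59 ± 0.23 (adjusted p = 0.000782). The largest decreases among genes of at least 1 CPM were those of Sdr16c6 (-7.65 ± 1.58, adjusted p = 0.00519), Pnpla5 (-7.40 ± 1.32, adjusted p = 0.00158) and Pnpla3. Vehicle values of these genes spread widely, with 20.9 ± 33.1 CPM for Sdr16c6 and 48.6 ± 77.6 CPM for Pnpla5. The largest increases were those of Acnat1, Gpr158 (3.02 ± 0.47, adjusted p = 0.000802) and Igfbp2, which encodes a binding protein of insulin-like growth factors (2.92 ± 0.54, adjusted p = 0.00223). Acnat1 (3.18 ± 0.92, adjusted p = 0.0378) rested on weight-matched library 27, at 104 CPM, without which its log2 fold change was -0.11. Vehicle libraries 4 and 6 weighed on some sizes: without them Pnpla3 stood at -3.89, Pnpla5 at -4.86 and Sdr16c6 at -5.58, all still called, and Acnat1 no longer passed (adjusted p = 0.105).

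Lipogenesis had a median log2 fold change of -0.86 and 14 calls adjusted over the list alone, 13 lower and 1 higher. By camera it was lower than other genes (adjusted p = 7.03e-08), with an adjusted p of 0.339 at an estimated correlation. Me1, the cytosolic malic enzyme gene, changed by -1.79 ± 0.37 (adjusted p = 0.00536). Thrsp, a regulator of lipogenesis also counted among thyroid hormone targets, changed by -1.06 ± 0.26 (adjusted p = 0.0170). Of 25 cholesterol synthesis genes 6 fell, or 11 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.000227, and 0.505 with an estimated correlation). Nsdhl, a sterol dehydrogenase gene, changed by -0.53 ± 0.12 (adjusted p = 0.0103). Mvd, the mevalonate diphosphate decarboxylase gene, changed by -1.45 ± 0.35 (adjusted p = 0.0134). Without vehicle libraries 4 and 6, lipogenesis still had 10 lower genes and a median of -0.45, whereas cholesterol synthesis had 1 lower gene and a median of -0.25, Me1 stood at -1.07 and Thrsp at -0.41, both still called, and Mvd at -0.81 no longer passed (adjusted p = 0.0678).

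Amino acid breakdown and urea synthesis had a median of -0.27, with 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.03e-05, and 0.460 with an estimated correlation). Among its members, Agxt, which encodes alanine-glyoxylate aminotransferase, changed by -1.21 ± 0.22 (adjusted p = 0.00164). From the gluconeogenesis and fasting list 3 of 15 genes fell, among them Sds, which encodes serine dehydratase (-1.77 ± 0.38, adjusted p = 0.00732), and Got1, an aspartate aminotransferase gene (-1.12 ± 0.26, adjusted p = 0.0107). The list as a whole was not called (camera adjusted p = 0.404). Fatty acid oxidation and ketogenesis genes had 2 of 29 lower, Cyp4a1 (-0.86 ± 0.21, adjusted p = 0.0139) and Hadh (-0.29 ± 0.08, adjusted p = 0.0311), and the list was not called (camera adjusted p = 0.0531). Among 17 bile acid genes 2 rose and 2 fell. Cyp7a1 (ENSRNOG00000009488), the rate-limiting enzyme of bile acid synthesis, rose from 99.1 ± 86.7 to 236 ± 73.4 CPM (1.25 ± 0.32, adjusted p = 0.0208). Cyp8b1, which sets the share of cholic acid, fell from 473 ± 94.8 to 243 ± 59.8 CPM (-0.96 ± 0.16, adjusted p = 0.00126), and the bile acid transporter Slco1b2 fell by 0.59 on the log2 scale (SE 0.11, adjusted p = 0.00180). With vehicle libraries 4 and 6 left out, the amino acid list had a median of -0.18 with 6 genes lower, and the rise of Cyp7a1 was 1.04 with an adjusted p of 0.0760.

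Of 24 xenobiotic and sex-biased cytochrome genes 5 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00772, and 0.348 with an estimated correlation). Ces1d, a carboxylesterase gene, rose by 1.51 ± 0.33 on the log2 scale (adjusted p = 0.00684), and Cyp3a62 by 0.78 ± 0.17 (adjusted p = 0.00636). Acute-phase genes had 3 of 15 lower, 4 adjusted over the list alone (camera adjusted p = 0.00266, and 0.375 with an estimated correlation). Among them, Crp, the C-reactive protein gene, fell from 5586 ± 927 to 4132 ± 217 CPM (-0.44 ± 0.09, adjusted p = 0.00515). Hp, the haptoglobin gene, fell by 0.60 on the log2 scale (SE 0.17, adjusted p = 0.0341). Igfals, which encodes a carrier of insulin-like growth factors, fell by 0.24 (SE 0.07, adjusted p = 0.0467). Igf1 itself stood at -0.51 ± 0.19 (adjusted p = 0.0947) and the hormone gene Fgf21 at 0.12 ± 0.29 (adjusted p = 0.829), neither past the test. With vehicle libraries 4 and 6 left out, Hp stood at -0.35 and was still called, Igfals no longer passed (adjusted p = 0.0750), Fgf21 passed at 0.70 (adjusted p = 0.0456) and Igf1 stood at -0.12. Scd, Cyp4a1, Cyp3a62, Ces1d and Acnat1 have close relatives in the rat genome, with which reads may have been shared.

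The count of 892 stood at 1042 without vehicle libraries 4 and 6, with 638 genes in common. A fit of the 2 groups alone called 414 genes. The count fell to 532 without vehicle library 6, 573 without weight-matched library 25, 579 without 26 and 586 without 27. The named genes past the test were called in all 16 fits that left out 1 library, except Hp in 10, Acnat1 in 8, Hadh in 7 and Igfals in 5.

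The comparison of CagriSema with vehicle in liver asked what the drug and the weight loss did together. Csad (ENSRNOG00000011573), which encodes the taurine-making enzyme cysteine sulfinic acid decarboxylase, rose from 127 ± 61.6 CPM (SD, n = 8) to 308 ± 87.2 CPM (n = 7). Pck1 (ENSRNOG00000028616), the rate-limiting enzyme of gluconeogenesis, fell from 3858 ± 831 to 2292 ± 360 CPM. Mt1, a metal-binding metallothionein gene, fell from 62.5 ± 24.7 to 16.6 ± 9.46 CPM. Igfals fell from 417 ± 40.8 to 326 ± 31.1 CPM.

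By edgeR's quasi-likelihood test, 45 genes passed, 14 higher and 31 lower with CagriSema, and 12 of them by more than 2-fold. The largest increases were those of Tbx20, a transcription factor gene (1.56 ± 0.31, adjusted p = 0.0433), Csad (1.28 ± 0.22, adjusted p = 0.0157) and Msln, the mesothelin gene (1.26 ± 0.25, adjusted p = 0.0433). The largest decreases were those of Adamts5, a matrix protease gene (-2.03 ± 0.41, adjusted p = 0.0434), Mt1 (-1.92 ± 0.41, adjusted p = 0.0449) and Acpp, an acid phosphatase gene (-1.75 ± 0.34, adjusted p = 0.0433). Pck1 changed by -0.75 ± 0.14 (adjusted p = 0.0433) and Igfals by -0.36 ± 0.08 (adjusted p = 0.0449). Scd (-1.81 ± 0.56, adjusted p = 0.136), Cyp7a1 (0.86 ± 0.33, adjusted p = 0.199), Igf1 (-0.54 ± 0.19, adjusted p = 0.177) and Fgf21 (0.20 ± 0.30, adjusted p = 0.743) did not pass. Leaving out 1 library let 2 of them pass, Cyp7a1 at 1.37 without vehicle library 7 (adjusted p = 0.00916) and Scd at -2.56 without CagriSema library 39 (adjusted p = 0.0436).

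Camera called 13 of 27 lists in this comparison, none of them with an estimated correlation (3 at an unadjusted p under 0.05). Amino acid breakdown was lower, with a median of -0.26 and 10 of 28 genes lower adjusted over the list alone, although none passed over all genes (camera adjusted p = 2.33e-06, and 0.421 with an estimated correlation). Fatty acid oxidation and ketogenesis had a median of -0.21 and 7 of 29 genes lower adjusted over the list alone (camera adjusted p = 3.89e-06, and 0.352 with an estimated correlation). Gluconeogenesis and fasting genes had a median of -0.31, with Pck1 the 1 gene of 15 that passed over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.00830, and 0.352 with an estimated correlation). Extracellular matrix genes were higher at a median of 0.37, with 3 of 19 higher adjusted over the list alone (camera adjusted p = 2.33e-06, and 0.325 with an estimated correlation). Lipogenesis was not called (median -0.22, camera adjusted p = 0.598). Oxidative phosphorylation genes had a median of -0.45 (camera adjusted p = 1.22e-07, and 0.640 with an estimated correlation), which became -0.02 without vehicle libraries 4 and 6. The same list went from -0.43 to 0.02 in the weight-matched comparison. In that fit for CagriSema against vehicle, no amino acid gene and no matrix gene passed adjusted over the list alone. Fatty acid oxidation genes had 4 lower and 1 higher there, and lipogenesis had a median of 0.04 with 4 higher and none lower, all adjusted over the list alone.

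Without vehicle libraries 4 and 6 the count was 18 genes, 11 of them among the 45, with Csad, Pck1 and Adamts5 still called and Tbx20, Msln, Mt1, Acpp and Igfals not (adjusted p from 0.0590 to 0.103). Fgf21 stood at 0.78 there (adjusted p = 0.107) and Igf1 at -0.15 (adjusted p = 0.471). A fit of the 2 groups alone called 4 genes. Leaving out 1 library gave 56 genes without vehicle library 2 and moved the count by over 1.5 times for every other library, from 3 without vehicle library 8 and 4 without CagriSema library 34 to 72 without vehicle library 4 and 130 without vehicle library 7. Csad was called in 14 of these 15 fits, all but the one without vehicle library 8, Pck1 in 9 and the other named genes in 4 to 6.

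The comparison of CagriSema with weight-matched rats in liver asked what the drug did beyond the weight loss. Of 19 genes of fat synthesis 2 were higher with CagriSema, and of 25 genes of cholesterol synthesis 3 were higher. Acly (ENSRNOG00000016924), which makes cytosolic acetyl-CoA for fat synthesis, stood at 728 ± 330 CPM (SD, n = 7) with CagriSema against 273 ± 59.0 CPM (n = 8). Acat2, an acetyl-CoA acetyltransferase gene, stood at 17.8 ± 8.94 against 6.94 ± 1.20 CPM. Igfbp2 was lower, at 2.67 ± 1.60 against 17.5 ± 16.0 CPM.

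Of 68 genes called by edgeR's quasi-likelihood test, 31 were higher and 37 lower with CagriSema, and 16 differed by more than 2-fold. Of the 68, 40 were also called for weight matching against vehicle, all 40 in the opposite direction. Only 3 were also called for CagriSema against vehicle, where the lipogenesis list was not called. The weight-matched libraries enter both comparisons, which favours opposite signs. A gene higher with CagriSema here may thus be one that food restriction lowered. The largest increases were those of Pnpla3 (4.35 ± 1.01, adjusted p = 0.0474), Trim36, a ubiquitin ligase gene (2.80 ± 0.41, adjusted p = 0.00560), and Acly (1.41 ± 0.30, adjusted p = 0.0273). The largest decreases were those of Igfbp2 (-2.70 ± 0.56, adjusted p = 0.0217), Vdr, the vitamin D receptor gene (-1.84 ± 0.37, adjusted p = 0.0202), and Hacl1, which encodes a peroxisomal lyase of fatty acid alpha-oxidation (-1.24 ± 0.28, adjusted p = 0.0424). Acat2 changed by 1.36 ± 0.27 (adjusted p = 0.0185) and Stat3, a transcription factor gene of the acute-phase list, by 0.54 ± 0.11 (adjusted p = 0.0253). Pnpla3 was the least even of these, with 379 CPM in CagriSema library 39 against 118 CPM or less in the other 6, and it was called in 2 of 16 fits that each left out 1 library. Scd (1.43 ± 0.54, adjusted p = 0.277), Cyp7a1 (-0.39 ± 0.33, adjusted p = 0.821), Igf1 (-0.03 ± 0.19, adjusted p = 0.995) and Fgf21 (0.08 ± 0.30, adjusted p = 0.987) did not pass, and Scd stood at 0.68 without CagriSema library 39.

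Among 19 lipogenesis genes 2 were higher over all genes, and 14 were higher and none lower adjusted over the list alone. Their median was 0.88 (camera adjusted p = 6.67e-12, and 0.155 with an estimated correlation). Among 25 cholesterol synthesis genes 3 were higher, or 18 adjusted over the list alone, and 24 had a positive fold change. Their median was 0.63 (camera adjusted p = 1.40e-17, and 0.277 with an estimated correlation). Without CagriSema library 39 the lipogenesis median was 0.75, the lowest of 15 fits that each left out 1 library of these groups. Markers of hepatocytes, a list added after the data were seen, had a median of 0.00 over 19 genes. Kupffer cell and macrophage markers had positive fold changes in 15 of 16 genes, at a median of 0.31 and with no single gene past the test (camera adjusted p = 0.00657, and 0.496 with an estimated correlation).

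The vehicle libraries entered this comparison through the fit shared by the 3 groups, in its spread, its scaling and the genes kept. Without vehicle libraries 4 and 6 it called 590 genes, all 68 among them, with 9 lipogenesis and 10 cholesterol synthesis genes higher and none lower. Without vehicle library 4 alone it called 335. Leaving out weight-matched library 25, 27, 28 or 31 gave 38, 29, 40 and 33 genes, and leaving out CagriSema library 35, 38 or 39 gave 44, 41 and 27. Trim36 and Acat2 were called in all 16 such fits, Vdr in 15 (not without CagriSema library 39), Igfbp2 in 11, Acly in 9, Stat3 in 8 and Hacl1 in 3.

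**Figure D2:**
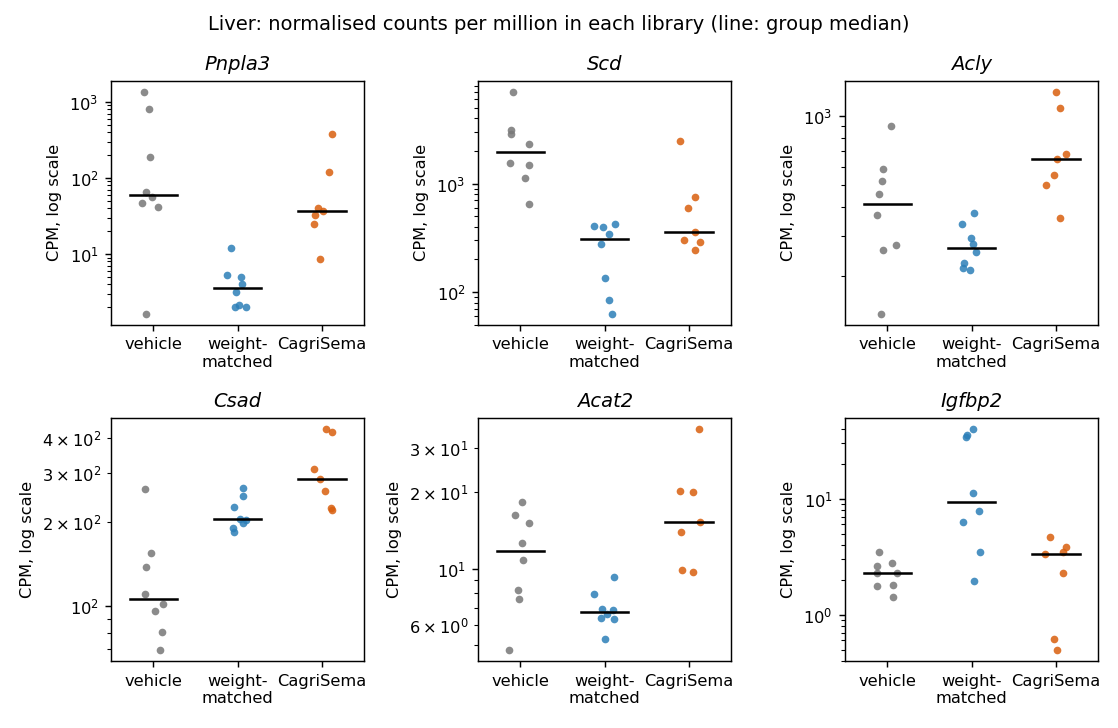
CPM of named genes in liver on a log axis, 1 point per library for the vehicle, weight-matched and CagriSema groups, with a line at the group median. Scd and Pnpla3 are lowest in weight-matched rats, and Acly averages 728 CPM with CagriSema against 273 CPM with weight matching.

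The responses to CagriSema and to weight matching were then set side by side in liver. Of the 892 genes called with weight matching, 852 (95.5%) had the same sign with CagriSema, at a median ratio of 0.533 of the size. Both comparisons used the same vehicle libraries, which gives agreement with no effect at all: in 20 simulations of unchanged groups, the 892 genes of lowest p had the same sign in 87.6% on average (highest 89.2%), at a median ratio of 0.507 (highest 0.549). The simulated vehicle libraries held none set apart, so agreement through vehicle libraries 4 and 6 is not in these simulated values. The agreement of called genes was not computed without vehicle libraries 4 and 6. With the vehicle libraries split between the comparisons, the share had a median of 77.2% (62.7% to 92.4%) and the ratio one of 0.284. Both lists of calls shared 7 genes that rose and 18 that fell. Simulated lists of the same lengths shared 7.3 and 12.75 on average (highest 11 and 18), and independent lists would share 0.348 and 1.41. Across 12702 genes the log2 fold changes correlated at r = 0.710, where genes are not independent replicates. Simulated unchanged groups gave r = 0.488, and giving each comparison its own part of the vehicle libraries gave a median r of 0.349 over 35 splits (0.153 to 0.494). The covariance was 0.0963 against 0.0236 in the simulation, a difference of 0.0727. Without vehicle libraries 4 and 6, r was 0.575 against 0.557 in the simulation (highest 0.588), the share of genes with the same sign was 68.75% against 68.81%, and the difference in covariance was 0.0306.

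In quadriceps, weight-matched rats were compared with vehicle rats in the same way. Of 21 matrix genes 11 fell, none rose and 10 did not pass the test. Col4a1 (ENSRNOG00000016281) and Col4a2 (ENSRNOG00000023972), the main chains of basement membrane collagen, fell from 110 ± 20.5 and 81.4 ± 13.9 CPM (SD, n = 7) to 59.6 ± 8.96 and 43.9 ± 6.73 CPM (n = 8). Of 19 genes of glycolysis and glycogen 8 rose, none fell and 11 did not pass. Gapdh, a glycolytic enzyme gene, rose from 4642 ± 741 to 6498 ± 740 CPM, and Pfkm, the muscle phosphofructokinase gene, from 3431 ± 613 to 4689 ± 315 CPM.

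By edgeR's quasi-likelihood test 285 of 12471 genes passed, 139 higher and 146 lower in weight-matched rats, and 24 by more than 2-fold. The largest increases were those of Fkbp5, a glucocorticoid-induced gene (1.39 ± 0.28, adjusted p = 0.0171), Slc7a2, a cationic amino acid transporter gene (1.12 ± 0.19, adjusted p = 0.00736), and Slc25a25, a mitochondrial ATP-Mg and phosphate carrier gene (1.11 ± 0.26, adjusted p = 0.0315). The largest decreases were those of Rrad, a small GTPase gene (-2.43 ± 0.58, adjusted p = 0.0357), Ptprn (-2.31 ± 0.59, adjusted p = 0.0420) and Actc1, the cardiac actin gene (-1.91 ± 0.48, adjusted p = 0.0395). Col4a1 and Col4a2 both changed by -0.89 ± 0.11 (adjusted p = 0.000128), and stayed called at -0.75 without vehicle libraries 2 and 5. None of the other 13 named genes past the test was called there, with adjusted p from 0.0559 for Slc7a2 to 0.462 for Ptprn, and Rrad, Ptprn, Actc1 and Ckb stood at -0.99, -0.71, -0.82 and -0.34. Gapdh changed by 0.49 ± 0.10 (adjusted p = 0.0129) and Pfkm by 0.45 ± 0.09 (adjusted p = 0.0149). Fbp2, the muscle fructose-bisphosphatase gene, rose by 0.86 ± 0.21 (adjusted p = 0.0319), and Ckb, a creatine kinase gene, fell by 0.54 (SE 0.14, adjusted p = 0.0478). Pik3r1 (0.46 ± 0.11) and Sesn1 (0.33 ± 0.08) of the insulin signalling list rose, each at an adjusted p of 0.0362.

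The matrix list had a median of -0.84 and 17 lower genes adjusted over the list alone (camera adjusted p = 6.33e-18, and 0.105 with an estimated correlation). The glycolysis list had a median of 0.40 and 13 higher genes adjusted over the list alone (camera adjusted p = 2.21e-13, and 0.105 with an estimated correlation). Genes of fast fibres had positive fold changes in 11 of 11, and all 11 passed adjusted over the list alone but 1 over all genes, Tnni2, the fast troponin I gene (0.34 ± 0.09, adjusted p = 0.0457). Their median was 0.37 (camera adjusted p = 1.45e-08, and 0.311 with an estimated correlation). Genes of slow fibres had negative fold changes in 13 of 13 at a median of -0.99, with none past the test over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00139, and 0.595 with an estimated correlation). Sln, the sarcolipin gene, stood at -1.21 ± 0.36 (adjusted p = 0.0709), Ucp3 at 0.91 ± 0.36 (adjusted p = 0.159) and Ucp2 at -0.55 ± 0.31 (adjusted p = 0.331). Sln passed without vehicle library 4 (adjusted p = 0.0490), while without vehicle libraries 2 and 5 it stood at -0.64 and Ucp2 at 0.00. Calcium handling genes were called upward by camera at a median of 0.19, while their mean was -0.03 (camera adjusted p = 0.0338, and 0.595 with an estimated correlation). Without vehicle libraries 2 and 5, the median of the matrix list was -0.53 with 11 lower adjusted over the list alone, that of calcium handling was 0.12, and no slow fibre gene passed adjusted over the list alone.

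The count of 285 rested on the vehicle libraries, and was 19 without vehicle libraries 2 and 5, all 19 among the 285, with 4 matrix genes still lower and no glycolysis gene past the test (12 adjusted over the list alone). It rested on the shared spread too, since a fit of the 2 groups alone called 7 genes. The count was 645 without vehicle library 1, 158 without 2, 46 without 5 and 436 without 6, and 111, 120, 105 and 110 without weight-matched library 25, 26, 28 or 30. Slc7a2, Gapdh, Pfkm, Col4a1 and Col4a2 were called in all 15 such fits, Fkbp5 in 14 (not without vehicle library 5), Slc25a25 in 11 and the other named genes in 4 to 8.

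In quadriceps of CagriSema rats, 3 of 21 matrix genes fell against vehicle. Sparc (ENSRNOG00000012840), which encodes a collagen-binding matrix protein, fell from 321 ± 62.7 CPM (SD, n = 7) to 201 ± 16.2 CPM (n = 8). Col4a1 fell to 73.2 ± 7.87 and Col4a2 to 53.9 ± 7.83 CPM. The fourth gene, Larp7, encodes a binding protein of the 7SK RNA and was named after its values were seen. By edgeR's quasi-likelihood test 4 genes passed, all 4 lower: Sparc (-0.67 ± 0.12, adjusted p = 0.0391), Col4a1 (-0.59 ± 0.11, adjusted p = 0.0391), Col4a2 (-0.59 ± 0.11, adjusted p = 0.0397) and Larp7 (-0.44 ± 0.08, adjusted p = 0.0391). At an unadjusted p under 0.05 there were 1287 genes. Of the 21 matrix genes 3 fell over all genes and 16 adjusted over the list alone, with 21 of 21 fold changes negative and a median of -0.63 (camera adjusted p = 1.40e-20, and 0.104 with an estimated correlation). Glycolysis genes had positive fold changes in 19 of 19 at a median of 0.18, none past the test (camera adjusted p = 2.59e-08, and 0.316 with an estimated correlation). Ucp3 (-0.87 ± 0.36, adjusted p = 0.397), Ucp2 (-0.63 ± 0.31, adjusted p = 0.485) and Sln (-0.50 ± 0.35, adjusted p = 0.635) did not pass, and Ucp2 and Sln stood at -0.07 and 0.07 without vehicle libraries 2 and 5.

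Without vehicle libraries 2 and 5 no gene passed by edgeR (603 at an unadjusted p under 0.05), and 9 matrix genes were lower adjusted over the list alone. On all libraries DESeq2 called 34 genes and limma voom none (855 at an unadjusted p under 0.05). Leaving out 1 library gave 7 genes without vehicle library 1, 6 or 8, and no gene by edgeR without vehicle library 2, 5 or 7 or without any 1 of the CagriSema libraries, where 894 to 1455 genes had an unadjusted p under 0.05. Sparc, Col4a1 and Col4a2 were each called in 4 of these 15 fits.

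Between CagriSema and weight-matched rats, 2 genes of mitochondrial carrier proteins, Slc25a25 and Ucp3, were lower in quadriceps. Slc25a25 (ENSRNOG00000014338) stood at 40.8 ± 11.6 CPM (SD, n = 8) with CagriSema against 128 ± 34.5 CPM (n = 8), and the lowest weight-matched library, at 90.5 CPM, lay above the highest CagriSema library, at 60.3 CPM. Ucp3 (ENSRNOG00000017716), the muscle uncoupling protein gene, stood at 23.4 ± 10.7 against 80.3 ± 45.5 CPM. Erfe, the gene of the iron-regulating hormone erythroferrone, was higher, at 4.39 ± 1.21 against 1.5 ± 1.03 CPM. By edgeR's quasi-likelihood test 16 genes passed, 6 higher and 10 lower with CagriSema. Of these 16, 8 were also called for weight matching against vehicle, all 8 in the opposite direction, and 0 for CagriSema against vehicle. The weight-matched libraries enter both comparisons, which favours opposite signs. The largest increases were those of Erfe (1.54 ± 0.29, adjusted p = 0.0230), Cpa1, a carboxypeptidase gene (1.02 ± 0.20, adjusted p = 0.0277), and Aplnr, the apelin receptor gene (0.83 ± 0.17, adjusted p = 0.0485). The largest decreases were those of Ucp3 (-1.78 ± 0.35, adjusted p = 0.0464), Slc25a25 (-1.64 ± 0.25, adjusted p = 0.00986) and Klf4, a transcription factor gene (-0.95 ± 0.19, adjusted p = 0.0464). Sln stood at 0.71 ± 0.35 (adjusted p = 0.661) and Ucp2 at -0.08 ± 0.30 (adjusted p = 0.976).

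Camera called 10 of 28 lists in this comparison, none of them with an estimated correlation (3 at an unadjusted p under 0.05) and none with any gene past the test over all genes. Slow fibre genes had positive fold changes in 13 of 13 at a median of 0.84 (camera adjusted p = 1.00e-07, and 0.413 with an estimated correlation), and fast fibre genes negative ones in 11 of 11 at a median of -0.31 (camera adjusted p = 1.11e-05, and 0.422 with an estimated correlation). Oxidative phosphorylation genes had positive ones in 46 of 46, at a median of 0.08 (camera adjusted p = 7.20e-06, and 0.806 with an estimated correlation). Glycolysis genes had a median of -0.20 (camera adjusted p = 3.52e-05, and 0.422 with an estimated correlation) and atrophy genes one of -0.12 (camera adjusted p = 0.0104, and 0.117 with an estimated correlation). Without vehicle libraries 2 and 5, Ucp3 (adjusted p = 0.0567) and Klf4 (adjusted p = 0.0644) no longer passed. Slc25a25 was called in 16 of 16 fits that left out 1 library, Erfe in 12, Cpa1 in 5, Ucp3 in 4, and Aplnr and Klf4 in 2. Leaving out weight-matched library 26, 28 or 29 gave 2, 4 and 3 genes, and leaving out CagriSema library 35, 36, 37 or 39 gave 6, 2, 10 and 10.

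**Figure D3:**
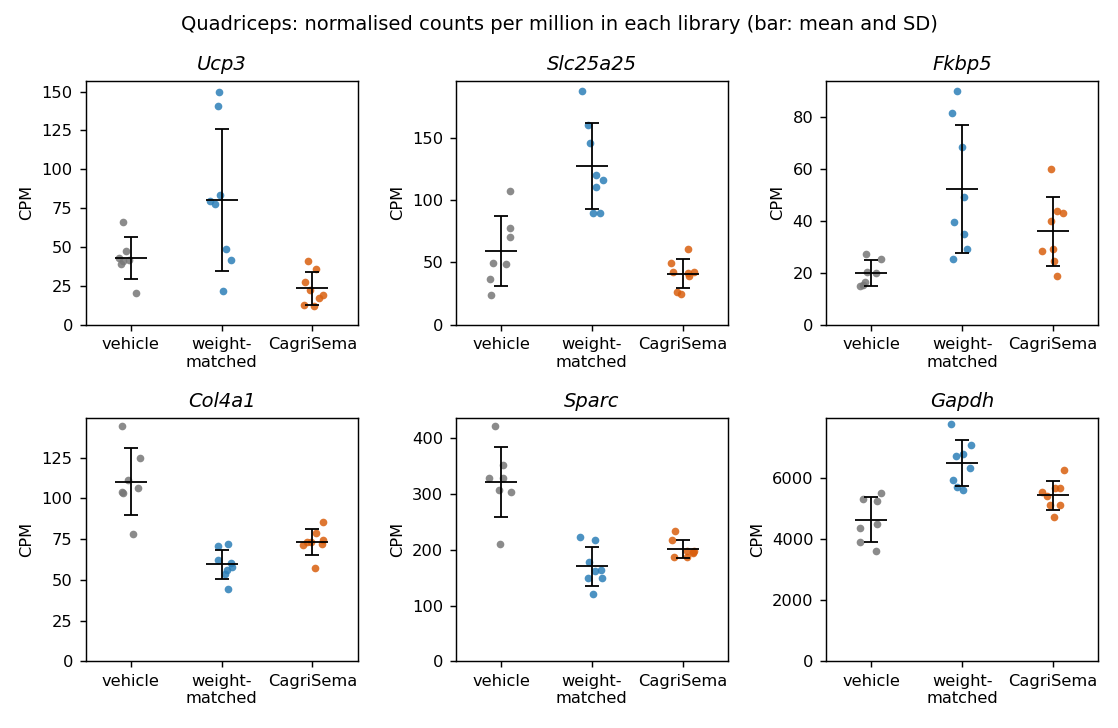
CPM of named genes in quadriceps on a linear axis, 1 point per library for the 3 groups, with the group mean and SD. Slc25a25 lies at 90.5 CPM or more in every weight-matched library and at 60.3 CPM or less in every CagriSema library.

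In quadriceps 278 of the 285 genes called with weight matching (97.5%) had the same sign with CagriSema, at a median ratio of 0.567 of the size. In the simulations of unchanged groups, the 285 genes of lowest p had the same sign in 94.0% on average (highest 95.8%), at a median ratio of 0.523 (highest 0.571). With the vehicle libraries split between the comparisons, the share had a median of 75.8% (33.7% to 89.1%) and the ratio one of 0.202. All 4 genes that fell with CagriSema, among them Sparc, Col4a1 and Col4a2, also fell with weight matching. Simulated lists of the same lengths shared 1.9 on average (highest 4), and independent lists would share 0.0468. The log2 fold changes correlated at r = 0.709 across 12471 genes, which are not independent replicates. Simulated unchanged groups gave r = 0.541, and giving each comparison its own part of the vehicle libraries gave a median r of 0.166 over 35 splits (-0.142 to 0.404). The covariance was 0.0495 against 0.0211 in the simulation, a difference of 0.0284. As in liver, the simulated vehicle libraries held none set apart. Unlike in liver, the correlation was not computed without the vehicle libraries that stood apart. Whether the excess over the simulation came through those libraries was therefore not tested in quadriceps.

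**Figure D4:**
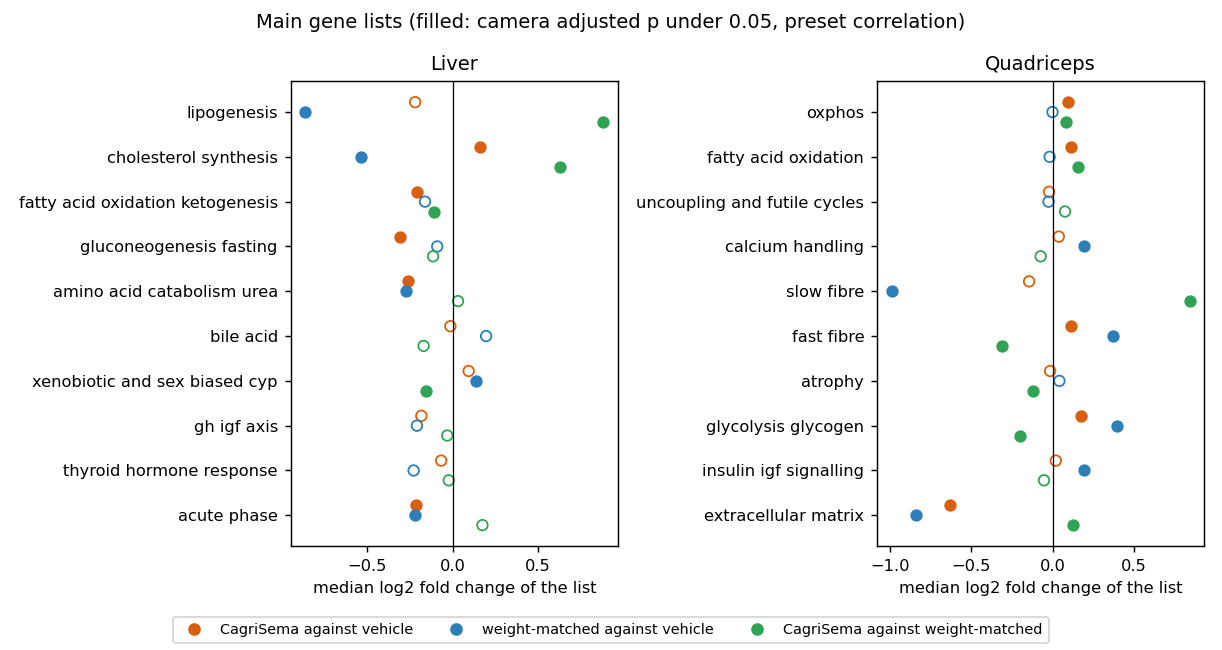
Median log2 fold change of each main gene list, fixed before the data were examined, in both tissues and all 3 comparisons. Matrix genes have medians of -0.84 and -0.63 against vehicle in quadriceps, and lipogenesis has 0.88 in liver for CagriSema against weight matching.

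Glp1r, the GLP-1 receptor gene, had 1 count in 1 of 23 liver libraries and 1 count in 1 of 23 quadriceps libraries. Calcr, the calcitonin receptor gene that forms amylin receptors with the Ramp proteins, had 0 counts in liver, which allows up to 0.00953 CPM over all 23 libraries. In quadriceps Calcr had 215 counts, spread over 23 of 23 libraries, with 0.572 ± 0.241 CPM (SD, n = 8) in CagriSema and 0.681 ± 0.255 CPM (n = 7) in vehicle rats, and did not pass in any comparison. Ramp1 and Ramp2 did not pass in either tissue, with log2 fold changes from -0.43 to 0.27. Ramp3 had 19 counts in liver and 57 in quadriceps and was not tested. Ucp1, the uncoupling protein of brown fat, had 1 count in quadriceps. These floors cover counting error only.

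Whether a change differed between the tissues was tested with an interaction over all 46 libraries. Weight matching changed 389 of 14110 genes differently, 194 with a higher and 195 with a lower log2 fold change in liver than in quadriceps. Oat fell in liver by 1.59 and stood at 0.29 in quadriceps, a difference of -1.88 ± 0.25 (edgeR quasi-likelihood adjusted p = 1.62e-05). Ldha, the lactate dehydrogenase A gene, differed by -1.60 ± 0.23 (adjusted p = 5.54e-05), the unnamed locus RGD1562690 by -1.66 ± 0.24 (adjusted p = 5.54e-05) and Mreg by -1.04 ± 0.15 (adjusted p = 7.75e-05). RGD1562690 stood at -1.31 in liver and 0.35 in quadriceps, near Ldha at -1.23 and 0.37, so the 2 may not be separate signals. CagriSema against vehicle gave 21 genes. Col6a2, a collagen VI chain gene, stood at 0.42 in liver and -0.57 in quadriceps, a difference of 0.99 ± 0.19 (adjusted p = 0.0102). Ccdc126 differed by -1.20 ± 0.20 (adjusted p = 0.00283), Rnf144b by -1.14 ± 0.19 (adjusted p = 0.00322) and the unnamed locus AABR07068316.1 by 1.35 ± 0.25 (adjusted p = 0.0102). CagriSema against weight matching gave 3 genes, among them Vdr (-2.05 ± 0.41) and Zpr1 (-0.73 ± 0.14), each at an adjusted p of 0.0445. With the library number as a replicate block across tissues no gene passed in this comparison. Vdr and Zpr1 were each called in 3 of 4 alternative fits.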

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

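Of the tests below, those of transcript length, of cell types in liver vehicle library 4, of hepatocyte share, of time of day, of fibre mix and of handling were chosen only after the results were seen, while those of single libraries and of other groupings of the libraries were set before.

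Within groups, 252 sets of values were searched for a library far from the others, and 43 held one, where chance gives about 1 in 20 for normal values, a rate not measured on these skewed and partly near-zero values. Liver vehicle library 4 accounted for 8 of them. Ribosomal protein genes took 1.84% of its counts. Its values were the highest of the group for Csad (249 CPM), Ramp1 (6.79 CPM), Ramp2 (7.02 CPM), Igf1 (1908 CPM), Got1 (613 CPM), Agxt (273 CPM) and Hp (21910 CPM). Liver vehicle library 6 was highest for mitochondrial share (9.29% of counts) and Scd (6941 CPM), and vehicle library 7 for Cyp7a1 (304 CPM).

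A candidate explanation for liver vehicle library 4 is a loss of long transcripts, as in degraded RNA. The log2 level of each gene was taken relative to its median over the liver libraries. Over 30 long and 26 short mRNAs, the median of the long minus that of the short was -3.11 in this library. It was -0.71 in vehicle library 6 and -0.26 to 0.18 in the other 21 liver libraries, which is what such a loss needs. Cells of another kind as the whole cause were argued against, since they would lower all hepatocyte mRNAs alike. Relative to the other vehicle libraries, long hepatocyte mRNAs had a median log2 level of -0.72 and short ones of 1.80, a difference of -2.51. Erythroid (1.56), pancreas (1.37) and adipocyte markers (0.99, 2 genes) were above the other vehicle libraries on the log2 scale, so a small share of other cells stays open beside the loss. No biological explanation was tested, since the labels set this library apart in no way.

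The higher medians of lipogenesis and cholesterol synthesis genes with CagriSema than with weight matching in liver were weighed next. A larger share of hepatocytes was argued against by hepatocyte markers, whose median log2 fold change was 0.0029 (SD 0.19 over 19 genes) where the lipogenesis median was 0.88. A single library was argued against by the medians without each library in turn, of which the lowest was 0.755 for lipogenesis and 0.541 for cholesterol synthesis. Clock genes argued against a large shift of the time of day at sampling. Their median absolute log2 fold change was 0.218 over 17 genes (highest 0.82). A smaller shift stays open even as the whole cause, since how far lipogenesis genes move with time of day was not measured. Camera also called the clock list lower (adjusted p = 0.0198, and 0.414 with an estimated correlation). An effect of the drug itself and a different pattern of meals in food-restricted rats may both give this pattern, and the design cannot separate them.

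The lower Ucp3 and Slc25a25 with CagriSema than with weight matching in quadriceps were the last pattern weighed. With a slow-fibre score per library as a covariate, Slc25a25 stood at -1.54 ± 0.27 (edgeR adjusted p = 0.0298) against -1.64 ± 0.25 before. Ucp3 stood at -1.78 ± 0.39 against -1.78 ± 0.35, so its size held while its adjusted p went from 0.0464 to 0.110 with the wider error. A different share of slow fibres was thus argued against as the cause of either fold. The score was built from slow-fibre genes only, so a shift among fast fibres was not tested. Another state of handling at sampling stays open: immediate-early genes in quadriceps went both ways at a median log2 fold change of -0.0636 (SD 0.62 over 15 genes), and in liver all 12 genes of that list had negative fold changes at a median of -0.49. A hypothesis left open is that food restriction raised both genes through fasting before sampling, which these data do not separate from a drug effect. Against vehicle, only Slc25a25 passed with weight matching. Ucp3 did not, and was called there in 0 of 25 alternative fits.

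Each count of changed genes was set against other groupings of the same libraries, 100 per tissue and 40 over both tissues, the real one included. In liver, 1 of 100 groupings, the real one, gave a count as large for CagriSema against vehicle (45, highest other 1), weight matching against vehicle (892, highest other 12) and CagriSema against weight matching (68, highest other 1). In quadriceps, the same held for CagriSema against vehicle (4, highest other 2) and weight matching against vehicle (285, highest other 1). For CagriSema against weight matching 2 of 100 groupings gave as many as the real 16, and the other one gave 53. Whether that grouping follows a trait of the libraries was not tested. For the differences between tissues, 1 of 40 groupings gave a count as large for CagriSema against vehicle (21, highest other 11), weight matching against vehicle (389, highest other 1) and CagriSema against weight matching (3, highest other 1). Each share is under 0.05, with no adjustment over these tests. The real grouping is among those drawn, so 1 of 100 and 1 of 40 are the lowest shares possible. Chance is not excluded for the quadriceps count of 16, which another grouping exceeded, nor for the counts between tissues at 1 of 40. Groupings over both tissues were also drawn within each tissue, without the library numbers that the tissues share.

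In the weight-matched livers, single libraries stood far above the rest for Mt1 (111 CPM in library 28), Acnat1 (104 CPM in library 27), Sdr16c6 (0.518 CPM in library 32), Pnpla3 (12.0 CPM in library 29), Cyp4a1 (117 CPM in library 25) and Hacl1 (1167 CPM in library 25). Oat was far below in library 27 (59.7 CPM), and 1 count of Glp1r in library 30 gave 0.0772 CPM. In the CagriSema livers, library 39 stood above the rest for Scd (2487 CPM), Sdr16c6 (31.2 CPM), Pnpla5 (26.1 CPM) and Pnpla3 (379 CPM). Library 38 was above for Acat2 (35.6 CPM) and below for Acnat1 (0.379 CPM). Cyp4a1 was above in library 40 (108 CPM), Igfals in library 35 (391 CPM) and Ramp3 in library 34 (0.311 CPM), while Acpp was below in library 36 (0.322 CPM).

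In quadriceps, vehicle library 5 stood apart by its TMM factor (1.13), Ucp2 (30.7 CPM) and Sln (37.9 CPM), and vehicle library 2 by Rrad (211 CPM) and Ptprn (20.2 CPM). In weight-matched rats, library 27 was above the rest for Rrad (18.2 CPM) and Ptprn (2.46 CPM) and library 29 for Actc1 (20.6 CPM), and 1 count of Glp1r in library 26 gave 0.0672 CPM. In CagriSema rats, the 10 most abundant genes took 28.3% of the counts of library 34, the highest of the group. Ramp1 was below the rest in library 33 (7.16 CPM), Rrad was above in library 40 (43.4 CPM) and Actc1 in library 39 (55.9 CPM), and 1 count of Ucp1 in library 38 gave 0.0826 CPM.

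Responses that differed between the tissues by the interaction test numbered 21 genes for CagriSema against vehicle, 389 for weight matching against vehicle and 3 for CagriSema against weight matching. With the library number as a replicate block across tissues these counts were 10, 282 and 0. The log2 fold change in liver minus that in quadriceps was -1.20 for Ccdc126, -1.14 for Rnf144b, 1.35 for AABR07068316.1 and 0.99 for Col6a2 with CagriSema against vehicle. It was -1.88 for Oat, -1.60 for Ldha, -1.66 for RGD1562690 and -1.04 for Mreg with weight matching against vehicle. It was -0.73 for Zpr1 and -2.05 for Vdr with CagriSema against weight matching.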

How the results depend on the processing

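The fits without liver vehicle libraries 4 and 6, without liver vehicle library 4 for CagriSema against weight matching, without quadriceps vehicle libraries 2 and 5, and with a slow-fibre covariate were chosen after the data were seen, and the others before. Of 2509 values of named genes under the alternatives, 2031 kept their direction and their side of the threshold, 437 kept the direction but no longer passed, 6 newly passed and 35 changed sign. Of genes past the test, only Acnat1 changed sign, in liver for weight matching against vehicle, at -0.10 with DESeq2 (adjusted p = 0.856) and -0.11 without weight-matched library 27, which alone held 104 CPM, and it was between -0.11 and 3.37 over all fits that left out 1 library. The other 33 sign changes were of genes past the test neither before nor after. With voom they were of Ramp1 (0.0873) and Ramp2 (0.279) in liver for CagriSema against vehicle, Ramp2 in liver for weight matching (0.221), Ramp1 in quadriceps for CagriSema against vehicle (0.123) and Calcr in quadriceps for weight matching (-0.0711). The fit without liver vehicle libraries 4 and 6 gave 0.0576, 0.207 and 0.120 for the first 3 of these. Without quadriceps vehicle libraries 2 and 5, Sln stood at 0.0733 for CagriSema against vehicle, and Calcr at -0.142, Ramp2 at 0.0453 and Ucp2 at 0.00357 for weight matching. With the slow-fibre covariate, Calcr (-0.0674) and Ramp2 (0.0496) changed sign for weight matching and Ramp1 (-0.119) for CagriSema against weight matching. Leaving out 1 library gave, in liver, -0.144 to 0.129 for Ramp1 and -0.148 to 0.222 for Ramp2 with CagriSema against vehicle, -0.236 to 0.134 for Ramp2 with weight matching, and -0.0256 to 0.170 for Fgf21 and -0.0537 to 0.0139 for Igf1 between CagriSema and weight matching. In quadriceps it gave -0.274 to 0.135 for Ramp1 with CagriSema against vehicle, -0.125 to 0.170 for Calcr and -0.182 to 0.0260 for Ramp2 with weight matching, and -0.147 to 0.0446 for Ucp2 between CagriSema and weight matching. No scaling moved the median of all genes by over 0.1. Unless said otherwise the cause of a change below was not tested.

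For CagriSema against vehicle in liver (45 genes), upper-quartile scaling gave 4, no filter 13, DESeq2 291, voom with quality weights 216, a fit of the 2 groups alone 4, the fit without vehicle libraries 4 and 6 18, and leaving out 1 library 3 to 130. For weight matching against vehicle (892), DESeq2 gave 1346, the 2 groups alone 414 and leaving out 1 library 532 to 1207. For CagriSema against weight matching (68), no filter gave 45, DESeq2 221, voom 617, the 2 groups alone 603, the fit without vehicle libraries 4 and 6 590, of which 68 were shared, and leaving out 1 library 27 to 335. Here the groups compared were the same, so the gain came through the fit they share with the vehicle libraries (the spread, the scaling and the genes kept). Against vehicle, the fits of the 2 groups alone went the other way, from 45 to 4 and from 892 to 414. Fewer libraries may account for part of that loss. Vehicle libraries 4 and 6 had quality weights of 0.0433 and 0.270, the lowest in liver. The p-values against vehicle may therefore be too small under the shared spread.

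For CagriSema against vehicle in quadriceps (4 genes), DESeq2 gave 34, voom 0 (855 at an unadjusted p under 0.05), the 2 groups alone 2, the fit without vehicle libraries 2 and 5 0 (603 at an unadjusted p under 0.05), the slow-fibre covariate 9, and leaving out 1 library 0 to 7. For weight matching against vehicle (285), no filter gave 131, DESeq2 693, voom 53, the 2 groups alone 7, the fit without vehicle libraries 2 and 5 19, and leaving out 1 library 46 to 645. For CagriSema against weight matching (16), no filter gave 7, DESeq2 34, voom 29, the covariate 7 and leaving out 1 library 2 to 17. The libraries that moved a count by over 1.5 times are named beside that count in the results.

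Camera called 13, 13 and 13 of 27 lists in liver and 9, 8 and 10 of 28 in quadriceps, for CagriSema against vehicle, weight matching against vehicle and CagriSema against weight matching. With an estimated correlation it called 0, 0 and 0 in liver (3, 2 and 2 at an unadjusted p under 0.05) and 0, 0 and 0 in quadriceps (3, 4 and 3). Fry called 3, 7 and 1 in liver and 1, 5 and 0 in quadriceps (4 for the last at an unadjusted p under 0.05). Without vehicle libraries 2 and 5, camera called 3 lists in quadriceps for CagriSema against vehicle.

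Genes whose change differed between tissues (21, 389 and 3) numbered 41 for CagriSema against vehicle and 13 for CagriSema against weight matching with the stricter filter, 34 and 69 without liver vehicle libraries 4 and 6, and 193, 802 and 50 with DESeq2. The correlation of fold changes fell from 0.710 to 0.349 in liver and from 0.709 to 0.166 in quadriceps with the vehicle libraries split between the comparisons, and to 0.575 in liver without vehicle libraries 4 and 6, where simulated unchanged groups gave 0.557 (highest 0.588). Over genes of at least 10 CPM it was 0.757 and 0.764. The split removes the shared libraries, and also leaves fewer per comparison. In quadriceps the correlation was not computed without the vehicle libraries that stood apart.

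No label says that a number in the titles marks 1 animal in both tissues. Over 9183 genes, deviations from the group means of the 22 shared numbers correlated between tissues at 0.0054 to 0.242, with 14 over 0.1. Their median was 0.117, against -0.0058 for pairs of unlike numbers. Of the 22 liver libraries, 13 correlated best with their own number. These values come from the data and not the design, and point to shared animals for many of the numbers. The tests between tissues without a block treat such libraries as unrelated. With the number as a replicate block, which left out 2 numbers, the tests between tissues gave 10 genes for CagriSema against vehicle, 282 for weight matching against vehicle and 0 for CagriSema against weight matching (968 at an unadjusted p under 0.05). Depth limits genes near 0.188 to 0.303 CPM in liver, where a library holds 3 counts.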

Other observations

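The tests below were of lists fixed before the data were examined, and the genes named from them were chosen after their values were seen. In liver, genes of the cell cycle list were lower with weight matching. Of its 13 genes 6 fell over all genes and 7 fell and 1 rose adjusted over the list alone, at a median log2 fold change of -0.72 (camera adjusted p = 0.000852, and 0.339 with an estimated correlation). Mcm5, a subunit of the replicative helicase, changed by -2.06 ± 0.44 (SE, adjusted p = 0.00701), and Top2a, which encodes a DNA topoisomerase of dividing cells, by -1.25 ± 0.36 (adjusted p = 0.0371), with n = 8 in both groups. Of 17 clock genes 5 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00933, and 0.339 with an estimated correlation). Among them Cry1, a repressor of the clock, rose by 0.86 ± 0.18 on the log2 scale (adjusted p = 0.00498), and Nr1d1, the gene of the repressor REV-ERB alpha, fell by 0.64 (SE 0.17, adjusted p = 0.0219). In quadriceps Nr1d1 fell by 0.78 (SE 0.17, adjusted p = 0.0191) with weight matching, and no clock gene passed there over all genes without vehicle libraries 2 and 5. Of 5 erythroid genes 3 fell in weight-matched livers, or 4 adjusted over the list alone, at a median of -1.67 (camera adjusted p = 0.00352, and 0.339 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells, changed by -1.99 ± 0.41 (adjusted p = 0.00495). In vehicle library 4 erythroid markers lay 1.56 above the other vehicle libraries on the log2 scale, which raises the vehicle mean of these genes. The cell cycle, clock and erythroid values of liver given here include vehicle libraries 4 and 6. Whether the erythroid fall reflects blood left in the samples was not tested.

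Proteasome genes had negative fold changes in 31 of 31 in weight-matched livers, where 6 fell over all genes and 16 adjusted over the list alone, at a median of -0.34 (camera adjusted p = 4.02e-09, and 0.505 with an estimated correlation). Without vehicle libraries 4 and 6 the median was -0.08, with 5 genes lower, or 9 adjusted over the list alone. For CagriSema against weight matching in liver the same list had positive fold changes in 31 of 31 at a median of 0.11, none past the test (camera adjusted p = 1.18e-05, and 0.496 with an estimated correlation), and 9 were higher without vehicle libraries 4 and 6. Immediate-early genes had negative fold changes in all 12 in that comparison at a median of -0.49, none past the test (camera adjusted p = 0.00501, and 0.414 with an estimated correlation). With CagriSema against vehicle, markers of stellate cells and fibroblasts in liver had 1 of 9 higher, Pdgfra, which encodes a growth factor receptor of mesenchymal cells (0.81 ± 0.17, adjusted p = 0.0449), or 3 adjusted over the list alone, at a median of 0.18 (camera adjusted p = 0.00345, and 0.296 with an estimated correlation). With vehicle libraries 4 and 6 left out, none of the 9 passed over all genes, and the median was 0.28. Extracellular matrix genes had a median of 0.37 in liver (0.27 and no gene past the test adjusted over the list alone in that fit) and -0.63 in quadriceps with CagriSema against vehicle. Of these genes, the difference between tissues was tested and passed for Col6a2, at 0.99 ± 0.19, and the lists were not tested against each other.

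In quadriceps, heat shock genes had a median of -0.39 with CagriSema against vehicle (camera adjusted p = 0.0227, and 0.793 with an estimated correlation), and it was -0.09 without vehicle libraries 2 and 5. Cell cycle genes had a median of -0.41 there, with 4 of 11 lower adjusted over the list alone and none over all genes (camera adjusted p = 0.0236, and 0.710 with an estimated correlation), and a median of -0.13 with none lower without those libraries. Of the denervation list 1 of 12 genes rose with weight matching, Dok7, a gene of the neuromuscular junction (0.31 ± 0.08, adjusted p = 0.0320), while 5 were lower and 1 higher adjusted over the list alone, at a median of -0.49 (camera adjusted p = 0.0321, and 0.440 with an estimated correlation). That median was -0.16 without vehicle libraries 2 and 5, where Dok7 no longer passed and none was lower adjusted over the list alone.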
